A study of Mus musculus with 12 samples.

How the data were processed

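RNA sequencing of whole mouse liver was analysed in 12 libraries made from total RNA with the SMARTer Stranded Total RNA kit. The deposited values are raw counts, whole numbers of reads per gene for 23420 genes, as produced with featureCounts. Per the submitters' processing notes, reads were handled with CASAVA 1.82, aligned with HISAT2 to mm10 (GRCm38) and counted with featureCounts. The headers of 4 of the count files name featureCounts 1.6.4, counting exons by gene, with no strand, pair or multiple-mapping option; reads were thus counted without regard to strand, and overlapping or near-identical genes can lose or share reads. Those 4 files hold the 7-week libraries, and the other 8 give no program line.

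Libraries were grouped by the genotype, age and treatment in their titles and descriptions, 2 per group. DKO replicates carry the numbers 2 and 3 in their titles, used here to name them, and 1 and 2 in their descriptions. No library was left out. Library totals ranged from 4939408 to 8776369 counts, so that 3 counts in a library correspond to 0.254 to 0.678 CPM. Transcripts of chromosome Y were present in all 12 libraries. Xist stood at 11.0 CPM in KO replicate 1 and 6.46 in DKO TAM replicate 1, against 0.961 and 0.501 in their fellow replicates and at most 1.78 in the other libraries; the cause was not tested.

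Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on the 6 groups with a minimum count of 10, TMM scaling, 1 group-means model over all 12 libraries (6 residual degrees of freedom, common biological coefficient of variation 0.124), a robust quasi-likelihood fit and the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Adjusted p-values of genes come from this test, and SE is the log2 fold change divided by the square root of F. CPM values are scaled by TMM, and their SD is over the 2 libraries of a group. With 2 libraries per group, the spread is estimated over all groups together.

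The contrasts were KO against FF, DKO against p53KO, DKO TAM against p53KO TAM, the effect in DKO minus that in KO, the effect in DKO minus that in DKO TAM, and p53KO against FF. The comparisons, the 31 gene lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined. The lists cover p53 targets, cell division, histones, hepatocyte metabolism and secretion, transcription factors, fetal and tumour genes, markers of other cell types, stress and inflammatory responses, the circadian clock, sex-biased genes and RNA polymerase II. Some genes stand on more than 1 list. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation and with fry, a test of whether a list moves as a whole. With an estimated correlation, 1 list remained called for KO against FF (p53 targets) and 1 for DKO TAM against p53KO TAM (plasma proteins).

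By the rule, Polr2m and Trp53 were always named. For each contrast, up to 6 genes per direction could be named with the largest fold change among called genes with a mean of at least 5 CPM in the higher group, no overlap between the groups and a protein-coding type. Up to 4 members with the smallest p were named per list, and list members could be named as checks of cell type or sex. Fewer were printed than the rule allows. A fold against a group with 0 counts is a lower bound against 3 counts over the group, and with 1 to 3 counts it is given with a 95% exact binomial interval; such bounds and intervals cover counting error only.

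Overlaps of called genes were compared with those expected of independent lists, with Fisher's exact test for lists. Deciles of expression came from control libraries of another experiment. Alternatives were RLE, upper quartile and library total scaling, leaving out mitochondrial, haemoglobin and ribosomal RNA genes, no expression filter, a filter of 1 CPM in 2 libraries with a mean of 10 counts, DESeq2 1.42.0, limma-voom, only the libraries compared, the replicate number as a block, each library left out, an adjusted p under 0.01 and an added 2-fold minimum. The method was tested on simulated data with the depths of these libraries. For the 3 main comparisons, 52%, 68% and 64% of 2-fold changes and 86%, 89% and 85% of 4-fold changes were recovered. False calls numbered 11, 8 and 9. In these data 200 genes changed, as many up as down, in a profile otherwise shared by all groups. The simulation therefore did not test the shift in composition of these livers or changes in as many genes as were called.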

Results

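Liver RNA from C57BL/6 mice was sequenced as 12 libraries that form 6 groups of 2 libraries. All groups carry floxed alleles of Gdown1, the product of the gene Polr2m, a protein that binds RNA polymerase II. FF livers keep Gdown1, and KO livers lose it in hepatocytes through Alb-Cre, a Cre recombinase under the albumin promoter; both were taken at 7 weeks. The p53KO and DKO livers were taken at 8 weeks, lack p53 (gene Trp53) and differ in the same Cre. The p53KO TAM and DKO TAM livers also lack p53 and were taken 24 hours after tamoxifen, which activates an inducible form of that Cre (Alb-CreERT2) in the DKO TAM group. The genotype given for p53KO TAM livers names no Cre, and their lack of it is read from that. Cre goes with the deletion in every comparison of deleted with control livers. Effects of Cre itself cannot be told apart from those of Gdown1 loss. Library totals ranged from 4939408 to 8776369 counts. Of 23420 genes, 13693 were tested, and they held 99.9% of the counts.

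Albumin mRNA took 5.44% ± 0.712 of all counts in FF and 3.20% ± 0.186 in KO livers (SD, n = 2). It took 5.93% ± 0.0340 in p53KO and 2.46% ± 0.354 in DKO livers, and 6.23% ± 0.0563 in p53KO TAM and 1.86% ± 0.0903 in DKO TAM livers. Fold changes below are on the TMM scale, which allows for such shifts in composition by taking most genes as unchanged. For DKO against p53KO, 7041 of 13693 genes were called, so that premise is uncertain there. These data do not settle which scale is right. Scaling by library totals alone moved the median log2 fold change of all genes up by 0.26 for KO against FF, by 0.77 for DKO against p53KO and by 0.35 for DKO TAM against p53KO TAM. Upper quartile scaling moved it up by 0.02, 0.22 and 0.03. The counts of list members that passed moved with the scaling too. The titles of 8 libraries carry numbers that differ between them, as numbers of separate animals would, but no label says what they stand for, and the other 4 titles carry none. The p-values measure the spread between these libraries.

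**Figure D1:**
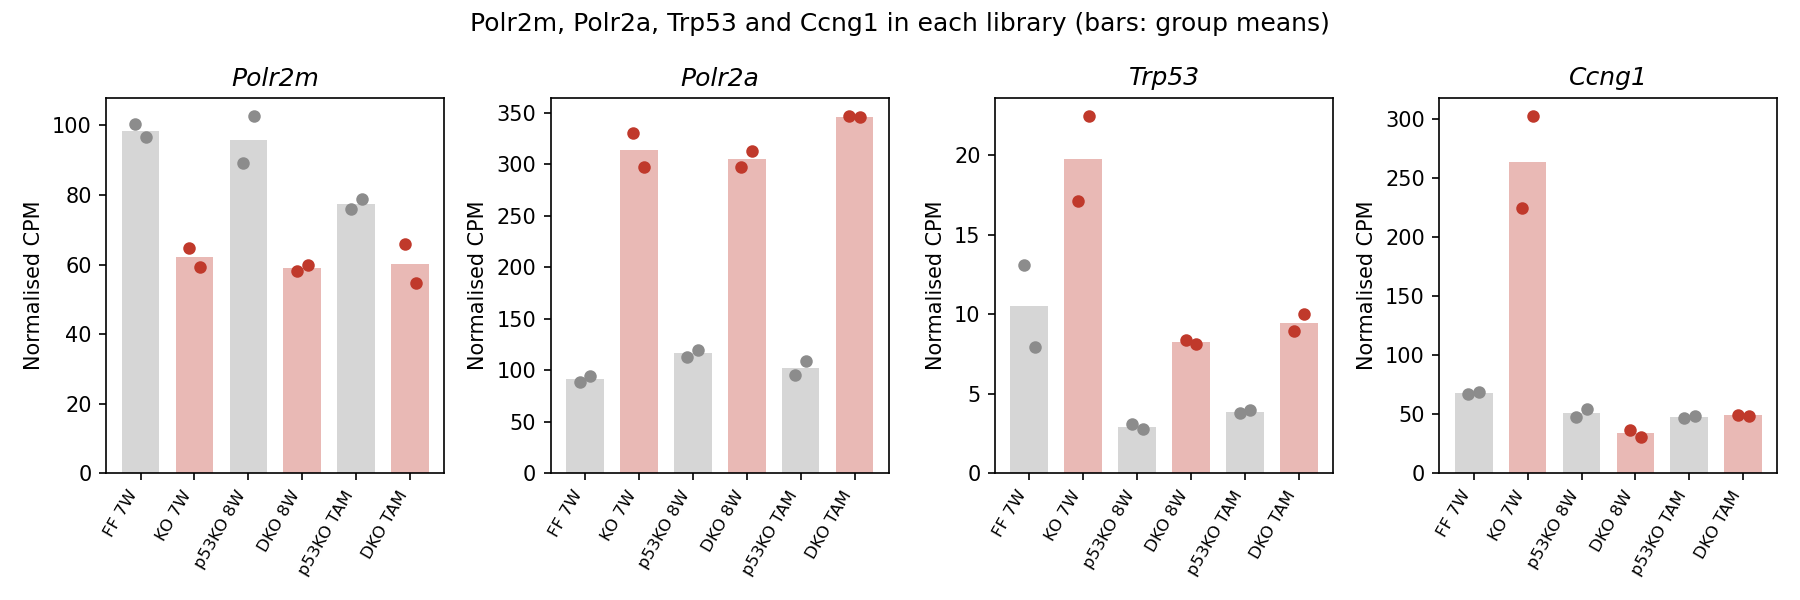
Normalised expression (CPM, library-scaled counts, vertical axes starting at 0) of Polr2m, Polr2a, Trp53 and Ccng1 in the 6 groups; points are the 2 libraries of a group, bars their mean, red for groups with Gdown1 deleted. On the TMM scale, mean Polr2m was 62.1 in KO and 98.5 in FF livers, Polr2a was higher in all 3 deleted groups, and Ccng1 was raised in KO livers at 263 against 68.2 CPM; with library totals alone the log2 fold change of Polr2m was 0.07 in DKO livers.

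The comparison of KO with FF livers asks what hepatocyte loss of Gdown1 changes while p53 is present. The lists of p53 targets and mitosis genes were called higher, and those of drug metabolism, amino acid catabolism, bile acid handling and plasma proteins lower. In none of these but the p53 list did a majority of members pass singly, and of these calls only that of the p53 list held with an estimated correlation. Polr2m (chromosome 9, 71478437 to 71485983, minus strand, mm10) fell to 62.1 ± 3.76 CPM from 98.5 ± 2.55 CPM (SD, n = 2), a log2 fold change of -0.67 ± 0.13 (SE, adjusted p = 0.0024). These counts cover the whole gene in whole liver, where other cell types keep the floxed alleles. Trp53 (chromosome 11, 69580359 to 69591873, plus strand) stood at 19.8 against 10.5 CPM (0.93 ± 0.24, adjusted p = 0.013), a call lost without FF replicate 2 (adjusted p = 0.20) or KO replicate 2 (0.14). In all, 2026 genes passed, 947 higher and 1079 lower, and 428 and 375 of them differed by at least 2-fold. With library totals alone, 2744 were higher and 550 lower. The count fell to 1230 and 1087 without FF replicate 1 or 2, and to 1285 and 1181 without KO replicate 1 or 2.

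Among 38 targets of p53, 27 rose (28 adjusted over the list alone, where 1 fell), with a median log2 fold change of 1.62 (camera adjusted p = 1.4e-30, and 0.045 with an estimated correlation). Ccng1, a cyclin induced by p53, rose from 68.2 to 263 CPM (1.95 ± 0.15, adjusted p = 3.7e-07). The death receptor Tnfrsf10b rose by 4.79 ± 0.41 and Zmat3, an RNA-binding tumour suppressor, by 2.42 ± 0.21 on the log2 scale. 9030617O03Rik (Dglucy), a glutamate cyclase, rose by 1.65 ± 0.13. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 73.7 against 0.997 CPM (6.21 ± 1.14, adjusted p = 0.015). That call was lost with limma-voom (adjusted p = 0.11), without FF replicate 1 (0.088) or 2 (0.12) and without KO replicate 2 (0.058). Eda2r, a receptor of the tumour necrosis factor family, rose by 5.25 ± 0.63, a call lost when only these 4 libraries were fitted (adjusted p = 0.071).

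The largest rises included transcripts near silence in control liver. Hrasls was at least 21.5-fold higher (0 counts in FF, with 3 counts over the group as floor), and Cox6b2, a testis form of a cytochrome oxidase subunit, was at least 17.8-fold higher. Psrc1, a spindle protein and p53 target, was 121-fold higher, with a counting interval of 21.3 to 4796. Cyp2b9, a cytochrome P450 typical of female liver, rose from 1.08 to 158 CPM. The largest falls were in major urinary protein genes, Mup7 (-7.07 ± 0.97) and Mup14 (-6.29 ± 0.75), whose near-identical copies share reads. Their calls were lost when only these 4 libraries were fitted (adjusted p = 0.12 and 0.062).

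Of 40 G2/M and mitosis genes, 19 rose (25 adjusted over the list alone), with a median of 1.37; the adjusted p was 5.6e-11, and 0.20 with an estimated correlation. Top2a, a topoisomerase of dividing cells, rose 3.10-fold to 20.6 CPM, the spindle motor Kif11 rose 2.44-fold and the transcription factor Mybl2 stood at 2.79 against 0.286 CPM. Of 40 G1/S and replication genes, 7 rose and 2 fell (the same counts adjusted over the list alone), with a median of 0.43 (adjusted p = 0.28 with an estimated correlation). This list missed the threshold without FF replicate 2 (adjusted p = 0.10), without KO replicate 1 (0.099) and with library totals alone (0.14). Of 35 replication-dependent histone genes, 6 rose (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.33 with an estimated correlation); library totals alone gave an adjusted p of 0.13.

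Transcripts of liver metabolism fell in several lists. Of 40 drug-metabolizing enzyme genes, 17 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -0.73. Gstp1, a glutathione transferase, fell from 388 to 106 CPM (-1.87 ± 0.17), Cyp2e1, a cytochrome P450 of central hepatocytes, by 3.19-fold and the sulfotransferase Sult1a1 by 2.66-fold. Of 42 amino acid catabolism and urea cycle genes, 17 fell and 1 rose (22 and 1 adjusted over the list alone). Ahcy, of the methionine cycle, fell 3.90-fold, Uroc1, of histidine breakdown, 2.32-fold and Tat, a tyrosine aminotransferase, 2.24-fold. Of 20 bile acid genes, 8 fell and 2 rose (12 and 2 adjusted over the list alone), among them the synthesis enzyme Cyp27a1 (-1.17 ± 0.14) and the uptake transporter Slco1b2 (-1.26 ± 0.19). The adjusted p of these lists was 0.26, 0.30 and 0.32 with an estimated correlation. For amino acid genes library totals alone gave 10 lower and 3 higher, with the median moving from -0.51 to -0.25; for drug genes the median moved to -0.48 and for bile acid genes from -0.62 to -0.36.

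Of 50 plasma protein genes, 18 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.32; the adjusted p was 6.7e-09, and 0.10 with an estimated correlation. That median was -0.06 with library totals alone, with 13 genes lower and 5 higher. Coagulation factor F11 fell 5.29-fold, the inter-alpha inhibitor Itih3 3.81-fold and Azgp1 2.37-fold. Of 24 fatty acid and triglyceride synthesis genes, 8 fell (9 fell and 1 rose adjusted over the list alone), led by Acacb, an acetyl-CoA carboxylase (6.58-fold), and Thrsp, a lipogenic regulator (4.25-fold). Of 25 cholesterol genes, 9 fell and 1 rose (12 and 1 adjusted over the list alone). Of 29 hepatocyte transcription factor genes, 10 fell (12 adjusted over the list alone), including Foxa1 (-0.90 ± 0.17) and the nuclear receptor Nr1i3 (-0.89 ± 0.17). The adjusted p was, with an estimated correlation, 0.32 for fatty acid synthesis, 0.49 for cholesterol and 0.20 for transcription factors. The medians of the fatty acid synthesis and transcription factor lists moved from -0.29 to -0.04 and from -0.33 to -0.08 with library totals alone, and that of cholesterol from -0.41 to -0.15, with 4 lower and 2 higher. Of 26 glucose and glycogen genes, 5 fell and 1 rose (5 and 2 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation), with a median of -0.16 that turned to 0.09 with library totals alone. Without FF replicate 2 that list had an adjusted p of 0.071, and without KO replicate 1 of 0.15. Fatty acid oxidation genes went both ways, 7 higher and 3 lower of 40 (7 and 4 adjusted over the list alone; adjusted p = 0.097), and the list passed without FF replicate 2 (0.037) or with library totals alone (0.049), where 18 were higher and 3 lower with a median of 0.44.

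Of 19 male-biased genes, 10 fell (11 fell and 1 rose adjusted over the list alone), with a median of -1.47 (adjusted p = 0.10 with an estimated correlation). The organic anion transporter Slco1a1 fell from 1760 to 136 CPM and Serpina1e 3.68-fold. Of 19 female-biased genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 1.27, or 0.96 with genes at 0 counts set to their bound (adjusted p = 0.20 with an estimated correlation, and 0.13 with library totals alone). Cyp2b13 was at least 12.9-fold higher. Of 26 interferon response genes, 9 fell (15 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), with Ifit1 4.02-fold, Rsad2 2.90-fold and Irf9 1.99-fold lower.

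Polr2a (chromosome 11, 69734410 to 69758223, minus strand), which encodes the catalytic subunit of RNA polymerase II, rose from 91.2 to 314 CPM (1.78 ± 0.13, adjusted p = 1.6e-07). Of 30 polymerase and pausing factor genes, 4 rose (4 adjusted over the list alone; adjusted p = 0.37 with an estimated correlation), including the elongation factor Supt5 (0.89 ± 0.14); with library totals alone 12 rose. Of 26 fetal liver and liver tumour genes, 4 rose (6 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). Of 25 stellate and fibroblast markers, 2 rose (2 adjusted over the list alone; adjusted p = 0.49 with an estimated correlation), as did 2 of 24 macrophage markers (1 adjusted over the list alone; 0.32 with an estimated correlation) and 2 of 14 cholangiocyte markers (3 adjusted over the list alone; list adjusted p = 0.097, and 0.0046 without FF replicate 1). The stellate list was lost without FF replicate 2 (adjusted p = 0.088), without KO replicate 1 (0.18) and with library totals alone (0.055), and the macrophage list without KO replicate 2 (0.091). With library totals alone 7 stellate, 11 macrophage and 5 cholangiocyte markers rose. The median of 22 endothelial markers was -0.11, and 0.15 with library totals alone (adjusted p = 0.52 and 0.73).

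The comparison of DKO with p53KO livers asks what hepatocyte loss of Gdown1 changes without p53. Genes of DNA replication and mitosis rose steeply, fetal liver genes and markers of cholangiocytes, fibroblasts and macrophages rose, and most measured genes of amino acid catabolism, plasma proteins and male-biased expression fell. All of these lists but that of fibroblasts kept their call with an estimated correlation. Polr2m stood at 59.0 ± 1.35 against 95.9 ± 9.64 CPM (SD, n = 2; -0.70 ± 0.13 SE, adjusted p = 2.4e-04), but at a log2 fold change of 0.07 with library totals alone (adjusted p = 0.65). Trp53 counts from the disrupted locus rose from 2.93 to 8.26 CPM (1.48 ± 0.29, adjusted p = 5.0e-04). In all, 7041 genes passed, 3516 higher and 3525 lower, and 2459 and 1357 of them differed by at least 2-fold. The split was 4662 and 2435 with upper quartile scaling and 8823 and 959 with library totals alone.

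Of 40 G2/M and mitosis genes, 39 rose and 1 fell (the same counts adjusted over the list alone), with a median of 4.76, or 4.72 with genes at 0 counts set to their bound (adjusted p = 2.9e-57, and 0.0055 with an estimated correlation). Top2a rose 32.1-fold from 6.38 to 205 CPM, Hmmr, a spindle-associated protein, 63.5-fold and Kif11 19.7-fold. The ubiquitin enzyme Ube2c was at least 40.5-fold higher and the spindle protein Troap at least 25.1-fold higher. Of 40 G1/S and replication genes, 33 rose and 1 fell (the same adjusted over the list alone), with a median of 1.88. The repair factor Brca1 rose 13.7-fold, the ribonucleotide reductase subunit Rrm2 12.9-fold and the replication clamp Pcna 3.05-fold. Of 35 histone genes, 24 rose and 1 fell (24 and 2 adjusted over the list alone), for example Hist2h2bb (2.71 ± 0.27). With an estimated correlation the adjusted p of these lists was 0.0055 and 0.038.

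All 42 amino acid catabolism and urea cycle genes fell (42 adjusted over the list alone), with a median of -1.84 (adjusted p = 2.7e-26, and 0.045 with an estimated correlation), but 39 did with upper quartile scaling and 31 with library totals alone, where the median was -1.07. Tdo2, the first enzyme of tryptophan breakdown, fell from 1753 to 186 CPM (9.42-fold), Haao of the same route 7.14-fold and Ahcy 7.12-fold. Of 50 plasma protein genes, 48 fell and 1 rose (the same adjusted over the list alone), with a median of -1.48 (0.0055 with an estimated correlation), or 36 lower, 2 higher and a median of -0.71 with library totals alone. Complement C8b fell 9.67-fold, Fetub 7.92-fold and F11 9.97-fold. Of 40 drug-metabolizing enzyme genes, 31 fell (33 adjusted over the list alone; adjusted p = 0.055 with an estimated correlation), with Cyp2e1 11.5-fold and Cyp2j5 8.61-fold lower. Of 20 bile acid genes, 18 fell (18 adjusted over the list alone; adjusted p = 0.057 with an estimated correlation), with Slco1b2 8.02-fold and Cyp27a1 4.23-fold lower. Library totals alone left 26 drug genes lower and 3 higher and 14 bile acid genes lower and 1 higher.

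On the TMM scale, transcripts of lipid and sugar metabolism fell with them. Of 24 fatty acid and triglyceride synthesis genes, 19 fell and 1 rose, and of 25 cholesterol genes 23 fell (the same counts adjusted over the list alone). Acacb fell 6.70-fold and the sterol enzyme Nsdhl 6.25-fold. For these lists the adjusted p was 0.068 and 0.15 with an estimated correlation, and library totals alone left 13 lower and 4 higher, and 16 lower and 1 higher. Of 26 glucose and glycogen genes, 22 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.026 with an estimated correlation), including the glucokinase regulator Gckr (4.88-fold) and the glycogen synthase Gys2 (4.50-fold); library totals alone gave 16 lower and 5 higher, with the median moving from -1.31 to -0.54. Of 40 fatty acid oxidation genes, 23 fell and 8 rose (23 and 9 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation), with a median of -0.50 that turned to 0.27 with library totals alone, where 18 rose and 9 fell. Of 29 hepatocyte transcription factor genes, 21 fell and 1 rose (22 and 1 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation), with Cebpa 3.67-fold and Nr1i3 3.40-fold lower. Only 9 of them fell and 5 rose with library totals alone, and the median moved from -0.80 to -0.04.

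All 19 male-biased genes fell (19 adjusted over the list alone; adjusted p = 0.014 with an estimated correlation), with a median of -4.01, or 15 and a median of -3.25 with library totals alone. Serpina1e fell 209-fold, from 7138 to 34.2 CPM, and Slco1a1 24.4-fold. The fatty acid elongase Elovl3 was 1180-fold lower, with a counting interval of 403 to 5728. Hsd3b5, a steroid enzyme, stood at 0.170 against 317 CPM, and Mup7 and Mup1, which share reads with their copies, at 0.767 against 2124 and 0.170 against 414 CPM. Of 19 female-biased genes, 9 rose (8 adjusted over the list alone; adjusted p = 0.057 with an estimated correlation, and 0.10 with library totals alone), among them the proton pump subunit Atp6v0d2 (1.84 ± 0.22). Sult2a1, a sulfotransferase typical of female liver, was at least 56.5-fold higher, and Krt20, a keratin of gut epithelium, at least 49.3-fold.

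Of 26 fetal liver and liver tumour genes, 25 rose (26 adjusted over the list alone), with a median of 2.80 (adjusted p = 0.0055 with an estimated correlation). Alpha-fetoprotein (Afp) rose 18.8-fold to 66.9 CPM, the Golgi protein Golm1 17.9-fold and the tubulin Tubb6 13.1-fold. Of 14 cholangiocyte markers, 12 rose (12 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation), with Prom1 15.2-fold and Epcam 9.20-fold higher. Of 25 stellate and fibroblast markers, 23 rose (24 adjusted over the list alone; adjusted p = 0.067 with an estimated correlation), with the matrix genes Lum 8.29-fold and Col1a2 7.57-fold higher. Of 24 macrophage markers, 23 rose (23 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation), including Gpnmb (0.429 to 35.9 CPM), Cd9 (5.03-fold) and the complement gene C1qa (2.71-fold).

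Endothelial markers stood apart, 2 of 22 higher and 6 lower (1 and 6 adjusted over the list alone), with a median of 0.06. The receptor Kdr fell 1.81-fold and the sinusoidal nuclease Dnase1l3 1.86-fold, calls lost with library totals alone (adjusted p = 0.59 and 0.44), where the list had 14 higher and a median of 0.82. The leukocyte gene Ptprc rose 2.99-fold, with 3 of 9 lymphocyte markers higher (2 adjusted over the list alone; list adjusted p = 0.088) and 3 of 7 neutrophil markers higher (2 adjusted over the list alone; 0.22). Of 6 erythroid genes, 3 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.26 with an estimated correlation), with the heme synthesis gene Alas2 6.01-fold lower. The erythroid call was lost with limma-voom (adjusted p = 0.088) and without an expression filter (0.23). Of 26 interferon response genes, 17 rose (17 rose and 1 fell adjusted over the list alone; adjusted p = 0.43 with an estimated correlation), with Oas2 4.12-fold and Mx1 3.68-fold higher. Of the 38 p53 targets, 14 rose and 8 fell (the same adjusted over the list alone), without a call for the list (adjusted p = 0.49). Scaling by library totals alone gave 26 higher and 2 lower, with a median of 1.03 (adjusted p = 0.95). Cdkn1a and Tnfrsf10b, chosen here after their values were seen, were also higher without p53. Cdkn1a stood at 10.6 and 31.9 CPM in the DKO libraries against 0 and 0.214 (adjusted p = 0.013), a call lost with limma-voom (0.16) and without p53KO replicate 1 (0.096) or 2 (0.066). Tnfrsf10b stood at 2.46 and 2.57 against 0.171 and 0.429 CPM (adjusted p = 3.1e-04). Pmaip1, a cell death gene, rose 4.50-fold and the kinase gene Plk3 fell 4.65-fold. Polr2a rose from 117 to 305 CPM (1.39 ± 0.12), with 7 polymerase genes of 30 higher and 2 lower (5 and 1 adjusted over the list alone; list adjusted p = 0.24, and 0.027 without p53KO replicate 1). With upper quartile scaling 14 of that list were higher and 1 lower, and with library totals alone 25 were higher, with a median of 1.02.

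The comparison of DKO TAM with p53KO TAM livers asks what had changed 24 hours after tamoxifen. The lists of plasma protein, drug metabolism, amino acid and lipid synthesis genes and of sex-biased genes of both kinds were called lower and that of mitosis genes higher. Of these calls only that of plasma proteins held with an estimated correlation. Polr2m stood at 60.3 ± 8.03 against 77.3 ± 1.99 CPM (SD, n = 2; -0.36 ± 0.13 SE), which missed the threshold (adjusted p = 0.063) and passed it without DKO TAM replicate 1 (-0.50, adjusted p = 0.040). Trp53 counts rose from 3.88 to 9.49 CPM (1.29 ± 0.28, adjusted p = 0.0039, and 0.052 without p53KO TAM replicate 1). In all, 2559 genes passed, 1179 higher and 1380 lower, 455 and 506 of them by at least 2-fold. With library totals alone, 4346 were higher and 586 lower. The count was 1188 and 1456 without p53KO TAM replicate 1 or 2 and 1438 without DKO TAM replicate 2.

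The albumin gene Alb fell from 72668 to 17060 CPM (-2.09 ± 0.18, adjusted p = 1.1e-06). Of 50 plasma protein genes, 35 fell and 2 rose (38 and 4 adjusted over the list alone), with a median of -0.68 (adjusted p = 1.0e-19, and 0.038 with an estimated correlation). Library totals alone gave 22 lower and 5 higher, with a median of -0.33. Itih3 fell 5.39-fold, F11 3.26-fold and Azgp1 2.61-fold. Of 40 drug-metabolizing enzyme genes, 23 fell (25 adjusted over the list alone), with a median of -1.02. The cytochrome P450 genes Cyp2c29, Cyp2d26 and Cyp2j5 fell 8.81-fold, 3.39-fold and 2.87-fold. Of 42 amino acid genes, 23 fell (31 adjusted over the list alone), with Uroc1 6.47-fold and Cbs, of homocysteine breakdown, 3.42-fold lower. With an estimated correlation the adjusted p of both lists was 0.14. Under library totals 19 drug genes were lower and 3 higher and 20 amino acid genes lower and 3 higher, with medians of -0.67 and -0.44.

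Of 24 fatty acid and triglyceride synthesis genes, 13 fell (16 fell and 2 rose adjusted over the list alone), with Thrsp 9.21-fold, Acacb 3.44-fold and the citrate lyase Acly 2.67-fold lower. Of 25 cholesterol genes, 11 fell (18 adjusted over the list alone), with Nsdhl 2.90-fold and Idi1 2.62-fold lower. Of 26 glucose and glycogen genes, 8 fell and 1 rose (10 and 1 adjusted over the list alone), with Gckr lower (-1.59 ± 0.14), and of 20 bile acid genes 8 fell and 1 rose (10 and 1 adjusted over the list alone). With an estimated correlation the adjusted p was 0.14, 0.33, 0.14 and 0.39 in that order. Scaling by library totals left 5 lower and 5 higher for glucose, with the median moving from -0.47 to -0.12, and 5 lower and 4 higher for bile acids, from -0.81 to -0.46. It left 9 lower and 3 higher for fatty acid synthesis and 7 lower for cholesterol. Of 26 unfolded protein and integrated stress response genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation); library totals alone gave 5 lower and 1 higher, with the median moving from -0.48 to -0.13. They included Herpud1 (3.10-fold), Atf5 (2.11-fold) and Xbp1 (1.69-fold), all of which serve protein folding or the response to its failure. The transcription factor list was not called (1 higher and 1 lower of 29, the same adjusted over the list alone; adjusted p = 0.10, and 5 higher with library totals alone, where the median turned from -0.27 to 0.08), nor was fatty acid oxidation (8 higher and 2 lower of 40, 10 and 5 adjusted over the list alone; 0.064). The second passed without p53KO TAM replicate 1 (adjusted p = 0.033), without DKO TAM replicate 2 (7.0e-04) and with library totals alone (0.020), where 25 were higher and 2 lower with a median of 0.55.

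Of 40 G2/M and mitosis genes, 28 rose (33 adjusted over the list alone), with a median of 1.79 (adjusted p = 1.0e-19, and 0.096 with an estimated correlation). Hmmr rose 8.12-fold, the spindle motor Kif20a 4.92-fold and the mitotic kinase Aurka 4.02-fold. G1/S and replication genes went both ways, 4 higher and 2 lower of 40 (3 and 1 adjusted over the list alone; list adjusted p = 0.33), and the thymidine kinase Tk1 fell 4.25-fold. Of 35 histone genes, 10 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.33 with an estimated correlation, and 0.35 with library totals alone), with Hist1h2ac 15.7-fold higher. The largest rises were again near-silent genes. Hrasls was 103-fold higher (counting interval 18.3 to 4108) and the plakophilin gene Pkp1 60.3-fold (10.6 to 2407). Igdcc4 and the receptor phosphatase Ptprz1 rose 23.1-fold and 21.3-fold. The largest falls included Ptgds, a prostaglandin synthase (84.2-fold), the trefoil peptide Tff3 (26.6-fold) and the transporter Slc22a26 (26.2-fold).

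Of 19 male-biased genes, 9 fell and 2 rose (the same adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). Serpina1e fell 10.8-fold and Slco1a1 4.08-fold, while C6 and Cyp2d9 rose 2.06-fold and 2.42-fold. Of 19 female-biased genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -1.23 (adjusted p = 0.096 with an estimated correlation). Cyp17a1, a steroid enzyme, fell from 131 to 16.0 CPM and Cux2, a repressor of male-biased genes, from 8.51 to 0.407 CPM. Of 22 endothelial markers, 9 fell (13 fell and 1 rose adjusted over the list alone; adjusted p = 0.33 with an estimated correlation), including Kdr (1.93-fold), the sinusoidal receptor Stab2 (1.88-fold) and Flt1 (1.73-fold); with library totals alone 3 fell and 2 rose. Of 24 macrophage markers, 3 rose (3 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation, and 0.060 without p53KO TAM replicate 2), among them Vsig4 (1.52-fold). Of 25 stellate and fibroblast markers, 4 fell (4 adjusted over the list alone; list adjusted p = 0.12, and 0.0048 without DKO TAM replicate 1), with Acta2 5.38-fold lower. That list's median was -0.26, and 0.09 with library totals alone. Cholangiocyte markers had 2 of 14 higher (2 adjusted over the list alone; list adjusted p = 0.070, with 0.034 without p53KO TAM replicate 1 and 0.030 without DKO TAM replicate 2). Of 26 fetal liver and liver tumour genes, 6 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.33 with an estimated correlation, and 0.093 with library totals alone).

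Polr2a rose from 102 to 346 CPM (1.77 ± 0.13, adjusted p = 1.7e-07), and 7 of the 30 polymerase and pausing genes rose (8 adjusted over the list alone; adjusted p = 0.33 with an estimated correlation), including the subunit gene Polr2b (1.51-fold); with library totals alone 20 rose. Of 38 p53 targets, 5 rose and 1 fell (3 and 1 adjusted over the list alone), without a call for the list (adjusted p = 0.28). The cytokine Gdf15 fell 3.50-fold. Tnfrsf10b, chosen here after its values were seen, stood at a mean of 1.32 against 0.323 CPM (adjusted p = 0.042), a call lost without any of the 4 libraries (adjusted p from 0.062 to 0.19). Of 26 interferon genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.63 with an estimated correlation). The interferon call was lost without p53KO TAM replicate 1 (adjusted p = 0.41) or DKO TAM replicate 2 (0.14).

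**Figure D2:**
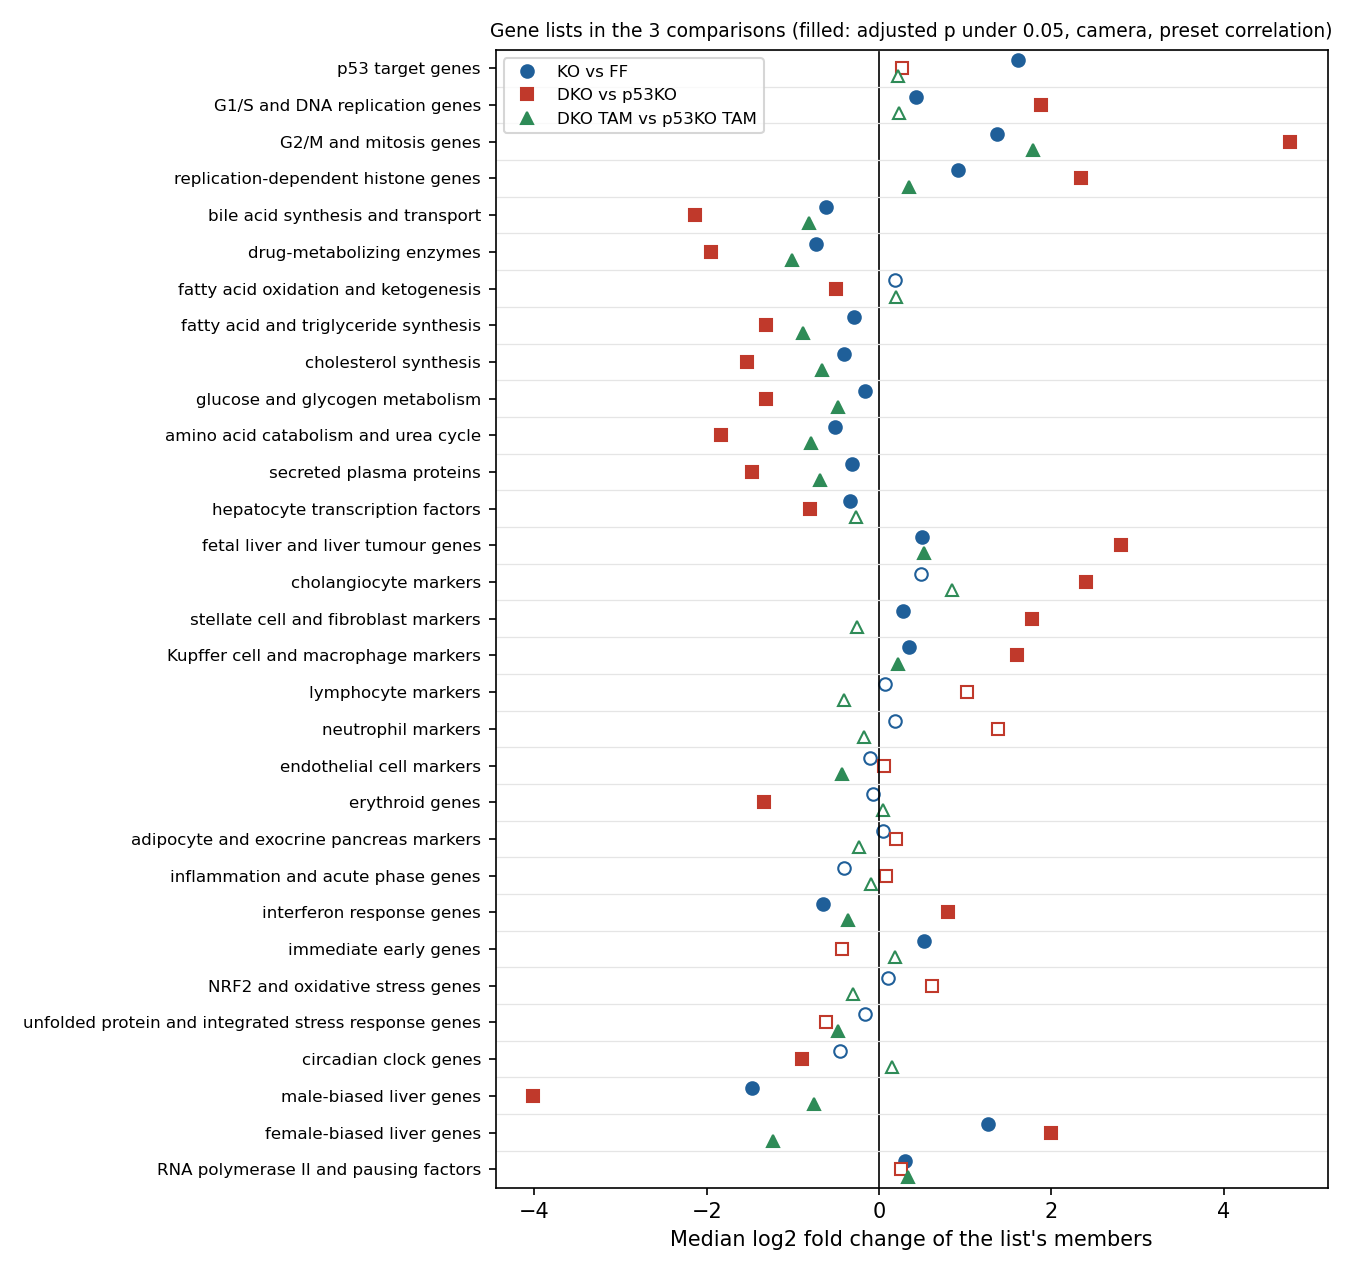
Median log2 fold change (horizontal axis) of the members of each of the 31 gene lists (vertical axis) in KO against FF (circles), DKO against p53KO (squares) and DKO TAM against p53KO TAM (triangles); filled marks passed the camera test with its preset correlation. G2/M and mitosis genes sat at 1.37, 4.76 and 1.79 and plasma proteins at -0.32, -1.48 and -0.68 in that order. With library totals alone the glucose list in KO livers turned to 0.09 and fatty acid oxidation in DKO livers to 0.27.

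The 3 comparisons share no libraries, and many of the same genes changed in all of them. In the same direction, 271 genes rose in all 3, where 20.9 would be expected of independent lists, and 507 fell, where 28.0 would be. Of 40 G2/M and mitosis genes, 17 were among those raised in all 3 (0.792 expected, Fisher's exact test, one-sided, adjusted p = 1.2e-17). Among those lowered in all 3 were 16 of 40 drug-metabolizing enzyme genes (adjusted p = 8.5e-12), 17 of 50 plasma protein genes (1.7e-11), 11 of 42 amino acid genes (1.9e-06), 8 of 19 male-biased genes (1.8e-06) and 8 of 24 fatty acid synthesis genes (9.0e-06). The cholesterol, unfolded protein, bile acid and glucose lists followed with 7, 6, 5 and 5 genes (adjusted p = 1.3e-04, 0.0014, 0.0026 and 0.0081). These p-values take genes as independent, which members of a list that move together are not, so they can be far too small. With an estimated correlation the drug-metabolizing enzyme, fatty acid synthesis, cholesterol, unfolded protein and bile acid lists were called in none of the 3 comparisons. Even with the preset correlation the unfolded protein list was not called in KO or DKO livers. Polr2a was called higher in each comparison.

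Between KO and DKO, 534 genes were shared higher (243 expected) and 871 lower (278 expected); between KO and DKO TAM, 400 (81.5) and 568 (109); between DKO and DKO TAM, 609 (303) and 944 (355). Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.570, 0.508 and 0.488 and Spearman's rho of 0.491, 0.475 and 0.394 for these pairs. The shared count of KO and DKO fell from 1405 to 749 without FF replicate 2, to 930 and 891 without KO replicate 1 or 2. That of KO and DKO TAM fell from 968 to 579 without FF replicate 2, to 641 without KO replicate 2 and to 585 without p53KO TAM replicate 1. That of DKO and DKO TAM fell from 1553 to 829 and 952 without p53KO TAM replicate 1 or 2 and to 928 without DKO TAM replicate 2.

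Genes were split into deciles of expression in control livers of another experiment. In the lowest decile, which ends at 1.29 CPM (1.23 for DKO TAM), 1.31% of genes were called lower in KO, 2.99% in DKO and 1.53% in DKO TAM livers, and 7.96%, 58.9% and 11.4% higher. At so few counts a fall can hardly be called, and genes there could pass the filter through high counts in another group, so these shares do not compare with those of abundant genes. Among deciles with ample counts, the share called lower was 10.7%, 38.6% and 12.6% in decile 8, from 39.5 CPM (40.8 for DKO TAM), and 19.7%, 68.5% and 27.2% in the top decile, from 135 CPM (139 for DKO TAM), where 5.62%, 6.13% and 5.33% were called higher. The power to call a change differs between these deciles too. The median log2 fold change of decile 8 was -0.02, -0.21 and -0.02. The median log2 fold change of the top decile was -0.11 ± 0.01, -0.64 ± 0.02 and -0.18 ± 0.02 (bootstrap SD across genes), and it turned to 0.14, 0.13 and 0.17 with library totals alone.

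**Figure D3:**
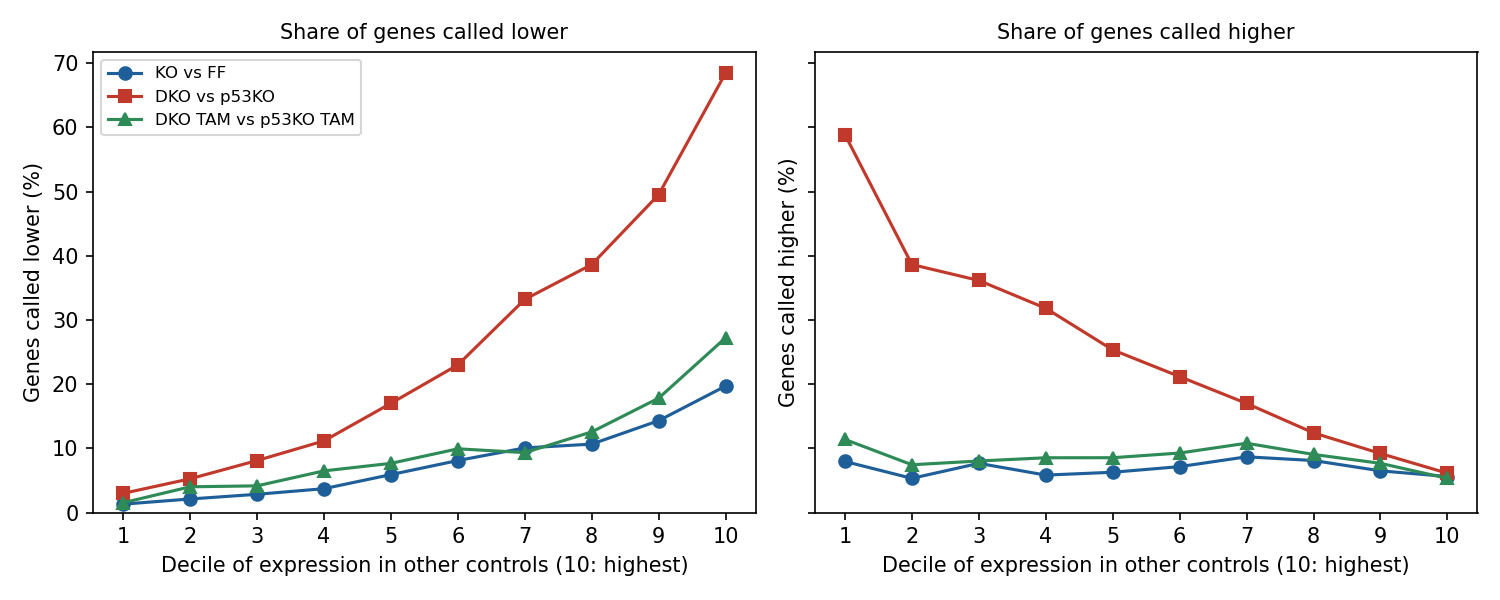
Share of genes called lower (left) and higher (right; vertical axes, percent, starting at 0) in each decile of expression (horizontal axes, 10 is the most abundant), for the 3 comparisons. In the top decile 19.7% were lower in KO, 68.5% in DKO and 27.2% in DKO TAM livers; at the few counts of the lowest deciles a fall can hardly be called, and the median of the top decile turned positive with library totals alone.

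The difference between the Gdown1 effects in DKO and KO livers was tested as an interaction; p53 status goes with the experiment and with age in this design. The effect on p53 targets and on 9 liver-function lists was lower in DKO livers, the rise of division genes was larger, and the effect on interferon genes was higher. Of these lists, fatty acid oxidation had gone both ways in KO livers and was not called there. Of the 22 lists called, 7 kept their call with an estimated correlation, among them 2 of the 9 liver-function lists, glucose and plasma proteins. Those of p53 targets and interferon genes did not keep theirs (adjusted p = 0.071 for both). The effect on Polr2m did not differ detectably (-0.03 ± 0.18, adjusted p = 0.92), nor did that on Trp53 (0.55 ± 0.38, adjusted p = 0.33, and 0.047 with library totals alone). In all, 3107 genes differed, 1335 higher and 1772 lower, or 1851 and 1077 with upper quartile scaling and 3588 and 499 with library totals alone. The count was 2034 without DKO replicate 3 and 1970 without FF replicate 1.

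Of 38 p53 targets, 18 had a lower effect in DKO livers (18 adjusted over the list alone), with a median difference of -1.03 (adjusted p = 4.6e-08, and 0.071 with an estimated correlation). Ccng1 differed by -2.54 ± 0.21, 9030617O03Rik by -2.51 ± 0.20 and Mdm2, the negative regulator of p53, by -1.75 ± 0.25 on the log2 scale. Mdm2 stood at 184 CPM in KO, 59.2 in FF, 54.2 in DKO and 58.5 in p53KO livers. Of 40 G2/M and mitosis genes, 34 had a higher effect (35 higher and 1 lower adjusted over the list alone), with a median of 3.39 (adjusted p = 0.021 with an estimated correlation). Top2a, Hmmr and Rrm2 differed by 3.37 ± 0.31, 4.47 ± 0.45 and 3.12 ± 0.45, and the checkpoint kinase Bub1 by 7.47 ± 0.85. Of 50 plasma protein genes, 41 had a lower effect (44 adjusted over the list alone; adjusted p = 0.0087 with an estimated correlation). Fetub stood at 49.8 CPM in DKO and 335 in KO livers, with controls at 394 and 348. Of 26 interferon genes, 22 had a higher effect (23 adjusted over the list alone; adjusted p = 0.071 with an estimated correlation), with Ifit1 differing by 2.82 ± 0.26 and Rsad2 by 2.09 ± 0.32. The matrix gene Lum (2.89 ± 0.31) and Alas2 (-2.72 ± 0.19) also differed.

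The difference between the effects at 8 weeks and 24 hours after tamoxifen, both without p53, goes with the experiment, the form of Cre and tamoxifen. Division genes and the markers of fibroblasts and macrophages gained more at 8 weeks, and the effect on female-biased genes differed. Of the 25 lists called, 9 kept their call with an estimated correlation, these among them. In all, 3782 genes differed, 1831 higher and 1951 lower, or 2336 and 1158 with upper quartile scaling and 3376 and 668 with library totals alone. Polr2m (-0.34 ± 0.18, adjusted p = 0.17) and Trp53 (0.20 ± 0.42, adjusted p = 0.76) did not differ detectably. Of 40 G2/M and mitosis genes, 33 had a higher effect at 8 weeks (36 adjusted over the list alone; adjusted p = 0.038 with an estimated correlation), with Top2a differing by 4.14 ± 0.29. Of 25 stellate and fibroblast markers, 22 did (22 adjusted over the list alone; 0.031 with an estimated correlation), with Col1a2 at 3.10 ± 0.31. Of 26 fetal liver genes, 18 did (21 adjusted over the list alone; 0.012 with an estimated correlation), with Vim at 2.83 ± 0.26. Of 19 female-biased genes, 11 had a higher effect (12 adjusted over the list alone; 0.012 with an estimated correlation), and of 19 male-biased genes 14 had a lower one (16 adjusted over the list alone; 0.017 with an estimated correlation). The female-biased list was called higher at 8 weeks and lower at 24 hours, but neither call held with an estimated correlation (adjusted p = 0.057 and 0.096). Levels in the controls differed too: Cyp2b9 stood at 0.534 CPM in p53KO and 147 in p53KO TAM livers, against 83.6 in DKO and 143 in DKO TAM livers. The macrophage elastase Mmp12 differed by 7.25 ± 0.56 and the phosphate transporter Slc34a2 by 7.58 ± 0.55.

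The comparison of p53KO at 8 weeks with FF at 7 weeks shows the controls side by side and mixes p53 status with age and experiment. Trp53 stood at 2.93 against 10.5 CPM (-1.81 ± 0.31, adjusted p = 0.0087), and the call was lost without p53KO replicate 1 (adjusted p = 0.070) or 2 (0.065) and without FF replicate 1 (0.11). Polr2m was at 95.9 and 98.5 CPM (-0.04 ± 0.13, adjusted p = 0.95). In all, 118 genes passed, 81 higher and 37 lower, with 1608 at an unadjusted p under 0.05, and 63 higher and 46 lower with library totals alone. The count was 49 and 62 without p53KO replicate 1 or 2 and 30 without FF replicate 1. Lpin1, a phosphatidate phosphatase, stood 9.22-fold higher and Mup5 34.7-fold lower. The signalling regulator Rgs16 was 6.58-fold higher, a call lost without FF replicate 1 (adjusted p = 0.11) or 2 (0.091). Of 23 immediate early genes, 4 were higher (15 higher and 1 lower adjusted over the list alone), with a median of 1.40 (adjusted p = 1.1e-21, and 0.14 with an estimated correlation). Among them, Zfp36 was 2.08-fold higher, and Dusp1 3.53-fold, a call lost without any of the 4 libraries (adjusted p = 0.10 and 0.12 without p53KO replicate 1 or 2, 0.17 and 0.11 without FF replicate 1 or 2).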

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

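The tests of the explanations below were chosen after the results were seen. Results are listed here because a test of the difference between experiments passed, and those experiments differ in age, p53 status, Cre or tamoxifen as well as in collection.

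For DKO against KO, 3107 genes differed in their change between Gdown1-deleted and control livers. The median log2 difference was -1.03 for p53 targets, 1.45 for G1/S and replication genes, 3.39 for G2/M and mitosis genes and 0.98 for histone genes. It was -1.44 for bile acid genes, -1.23 for drug-metabolizing enzymes, -0.76 for fatty acid oxidation, -0.92 for fatty acid synthesis, -1.06 for cholesterol, -0.94 for glucose and glycogen, -1.28 for amino acid catabolism, -1.05 for plasma proteins and -0.52 for hepatocyte transcription factors. It was 2.37 for fetal liver genes, 1.88 for cholangiocyte, 1.35 for stellate and fibroblast, 1.26 for macrophage and 0.86 for lymphocyte markers, -1.50 for erythroid genes, 1.02 for inflammation genes, 1.597 for interferon genes and -2.13 for male-biased genes. Of these 22 lists, 7 stayed called with an estimated correlation: G1/S, G2/M, glucose, plasma protein, fetal liver, macrophage and male-biased genes. Among genes, Ccng1 differed by -2.54, 9030617O03Rik by -2.51, Mdm2 by -1.75, Bub1 by 7.47, Serpina1e by -5.83, the esterase Ces3b by -4.69, Top2a by 3.37, Hmmr by 4.47, Rrm2 by 3.12, Fetub by -2.93, C8b by -2.80, Lum by 2.89, Tubb6 by 3.53, Ifit1 by 2.82, Rsad2 by 2.09 and Alas2 by -2.72. Calls for histones (without p53KO replicate 2, adjusted p = 0.053), lymphocytes (without FF replicate 2, 0.081), erythroid genes (without KO replicate 1, 0.095, and FF replicate 2, 0.050) and inflammation (without p53KO replicate 2, 0.068, FF replicate 2, 0.15, and KO replicate 1, 0.096) each rested on single libraries. Without DKO replicate 3 the count of genes was 2034, and without FF replicate 1 it was 1970.

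For 8 weeks against 24 hours, 3782 genes differed. The median log2 difference was 1.72 for G1/S and replication genes, 3.14 for G2/M and mitosis genes, 1.16 for histone genes, -1.38 for bile acid genes, -1.12 for drug-metabolizing enzymes, -0.72 for fatty acid oxidation, -0.59 for fatty acid synthesis, -0.86 for cholesterol, -0.72 for glucose and glycogen, -0.93 for amino acid catabolism, -0.98 for plasma proteins and -0.73 for hepatocyte transcription factors. It was 2.43 for fetal liver genes, 1.55 for cholangiocyte, 2.17 for stellate and fibroblast, 1.44 for macrophage, 1.71 for lymphocyte and 1.86 for neutrophil markers, -1.32 for erythroid genes, 0.50 for inflammation, 1.17 for interferon, 0.87 for NRF2, -1.02 for clock, -2.58 for male-biased and 4.16 for female-biased genes. Of these 25 lists, 9 stayed called with an estimated correlation: G1/S, G2/M, plasma protein, transcription factor, fetal liver, stellate, macrophage, male-biased and female-biased genes. Slc34a2 differed by 7.58, Mmp12 by 7.25, the surface protein Ly6d by 7.34, the bile acid enzyme Cyp7b1 by -4.46, Top2a by 4.14, Brca1 by 2.96, Col1a2 by 3.10, Vim by 2.83, Atp6v0d2 by 3.16, Cyp17a1 by 2.94, Tdo2 by -2.82, C8b by -2.37, Npas2 by 3.64 and Arntl by 2.48. The neutrophil call was lost without p53KO replicate 2 (adjusted p = 0.087), DKO replicate 3 (0.075), p53KO TAM replicate 1 (0.10) or DKO TAM replicate 1 (0.10). The erythroid call was lost without DKO TAM replicate 1 (0.092) or p53KO replicate 2 (0.050), the inflammation call without p53KO replicate 2 (0.071) or DKO TAM replicate 1 (0.29), and the histone call without p53KO replicate 2 (0.050).

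Some genes near silence in control livers were higher in the Gdown1-deleted livers of every experiment. Of 1053 tested genes with a control mean under 1 CPM, 45 were higher in all 3 comparisons. Of independent calls 7.91 would be expected. Genes so scarce in controls could pass the filter through high counts in deleted livers, and 694 of them were called higher in DKO livers. That expected number thus rests on genes partly chosen for rising. The medians of the 45, at 3.30, 4.64 and 2.92, follow from their choice. Those of the whole lowest decile of expression were 0.51, 1.93 and 0.39. Reads running in from active genes nearby would give the 45 active neighbours more often than genes that did not rise. A gene of at least 5 CPM lay within 10 kb on either strand for 37.8% of them (95% interval 23.8 to 53.5). The share was 43.6% for 1008 other near-silent genes, a ratio of 0.867. Many of those others were called higher in DKO livers and could hold such reads too, so this test cannot decide. A narrower test of upstream neighbours on the same strand, run first, gave 7 of 45, too few to decide.

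The rules for scaling and division were rewritten after earlier forms of these tests had left both open. Scaling of the libraries moves all genes of a library by 1 factor. Near-silent genes called higher in 1 comparison exceeded others in another by 0.422 to 2.02 in the median. The smallest differences, 0.422 and 0.497, missed a margin of 0.5 set at first. Within strata of control level the intervals of 4 of the 6 pairs stayed above 0, at least 1 in each comparison, and the smallest of the clearer pairs was 1.07 (0.88 to 1.30). The 2 intervals that held 0 were of genes chosen in DKO livers. Scaling therefore does not explain the whole pattern, though it can add to the size of the rises. Reads from dividing cells would make the set gain at 8 weeks over 24 hours as mitosis genes do. A first test on the 41 genes outside the division lists decided nothing, since genes such as Troap were among them. The whole set gained less than the 13 other G2/M genes higher in all 3 comparisons, a difference of -1.79 (-2.48 to -0.28). Of the 45, 8 did not gain. Both changes that make up the gain were used to choose these genes. A scarce gene needs a larger rise at 24 hours to be called, which lowers its gain, so this test cannot decide. The gain of 13 single genes of the set lay below that of the mitosis genes, which none of the latter did by the same measure. The same limit holds there, and division stays open for all 45. A loss of restraint on RNA polymerase II at weakly used promoters stays a hypothesis, found on these data and not tested by any measure of the polymerase itself.

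Liver-function lists fell while fibroblast, macrophage and cholangiocyte markers rose in DKO livers. A lower share of hepatocytes alone would raise the markers of every other cell type alike. Yet on the TMM scale endothelial markers had a median of 0.0562 (95% interval -0.40 to 0.21). Macrophage markers stood at 1.5998 (1.21 to 2.32), stellate and fibroblast markers at 1.77 (1.10 to 2.92) and cholangiocyte markers at 2.41 (1.84 to 3.20). Library totals alone moved all genes up by 0.77 in the median, so that endothelial markers rose too. That shift moves these lists alike and leaves the gap between them. The plasma protein list kept a median of -0.71 (95% interval -1.02 to -0.52) with library totals alone. Its fall thus does not hang on the choice between TMM and library totals, but a larger shift of all genes was not tested. Of the 8 other liver-function lists, 6 kept an upper bound below 0 with library totals alone. Across these lists scaling cannot be excluded, since transcription factors had a median of -0.04 (-0.38 to 0.19) and fatty acid oxidation 0.27 (-0.08 to 0.54). The markers are whole-tissue lists, and hepatocytes can also express some of the fetal and cholangiocyte genes. More macrophages and fibroblasts, or changed expression within cells, stay open.

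Clock genes differed between deleted and control livers, which could come from the hour of collection or from feeding. An index of clock phase (Arntl, Npas2 and their opposite-phase partners) was higher in deleted than in control livers by 2.73 in KO and 2.81 in DKO but lower in DKO TAM by -1.62, with SDs of 1.21 in DKO TAM and 0.58 in p53KO TAM livers. Both DKO TAM libraries (-0.69 and 1.03) lay below their controls (1.38 and 2.20), but this difference was not tested. With 2 libraries per group it speaks only against a shift of hour in the same direction as a cause of the 507 genes lowered in all 3 comparisons. Feeding, which the index does not measure, stays open for them. For genes called in KO or DKO alone, hour and feeding both stay open. The index was 0.21, 0.02 and 0.17 in the KO, DKO and DKO TAM groups and -2.52, -2.79 and 1.79 in their controls. A flattened clock in deleted livers is a hypothesis that samples from several hours of the day would test.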

How the results depend on the processing

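All alternatives here were planned. Of the gene results named, 42 of 47 calls for KO against FF, 58 of 62 for DKO against p53KO and 47 of 50 for DKO TAM against p53KO TAM kept their side of the threshold under all alternative fits, as did 16 of 16 and 14 of 14 for the differences and 3 of 6 for p53KO against FF. Of the lists called, 13 of 20, 18 of 21, 13 of 17, 18 of 22, 21 of 25 and 2 of 6 did. These counts leave out the stricter thresholds and, for lists, the estimated correlation and fry. With an estimated correlation 1, 11, 1, 7, 9 and 0 lists were called in the same order. Turned in direction with library totals alone: the median of the top decile of expression (0.143 for KO, 0.130 for DKO, 0.167 for DKO TAM) and Polr2m in DKO (0.0685). Medians of lists not called turned too: endothelial (0.150), erythroid (0.184) and unfolded protein genes (0.0842) in KO, immediate early (0.330) and unfolded protein genes (0.154) in DKO, and transcription factor (0.0832), stellate (0.0894), neutrophil (0.164), adipocyte and pancreas (0.111), inflammation (0.254) and NRF2 genes (0.0430) in DKO TAM, as did those of glucose genes in KO (0.0870) and fatty acid oxidation in DKO (0.270), which were called. TMM removes the shift of all genes in that setting; otherwise the cause was not tested. Groups of 2 leave the size of small changes uncertain, and leaving 1 library out assumes that the lone library varies like the other groups.

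Genes called with library totals alone were 3294 for KO and 4932 for DKO TAM. At an adjusted p under 0.01 they were 960 for KO, 1201 for DKO TAM, 1545 for DKO against KO, 2069 for 8 weeks against 24 hours and 37 for p53KO against FF. With a 2-fold minimum they were 803, 3816, 961, 1888, 2348 and 68 for KO, DKO, DKO TAM, both differences and p53KO against FF. For the last, no expression filter gave 190 and DESeq2 182. Lists called with a 2-fold minimum were 4 for KO, 3 for DKO TAM, 16 for 8 weeks against 24 hours and 1 for p53KO against FF. With an estimated correlation they were 1, 11, 1, 7, 9 and 0, and for p53KO against FF camera with its preset correlation called 6 and fry 0. Shared calls with library totals alone were 2714 for KO and DKO, 2131 for KO and DKO TAM and 3892 for DKO and DKO TAM; at 0.01 they were 681, 416 and 767, and with a 2-fold minimum 578, 360 and 607. The median of the top decile was -0.0872, -0.422 and -0.151 for KO, DKO and DKO TAM with upper quartile scaling. For DKO it was -0.605 with the stricter filter, -0.602 with only the libraries compared and -0.702 by reads per kilobase, which gave -0.202 for DKO TAM. The strict thresholds count fewer genes by construction; for the others the cause was not tested.

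Leaving out each library in turn gave 1087 to 1285 genes for KO, 5529 to 6246 for DKO, 1188 to 1952 for DKO TAM, 1970 to 2751 for DKO against KO, 2550 to 3442 for 8 weeks against 24 hours and 30 to 105 for p53KO against FF. Lists called ranged from 18 to 22, 20 to 22, 17 to 20, 20 to 24, 22 to 25 and 4 to 11. Shared calls ranged from 749 to 1317 for KO and DKO, 579 to 807 for KO and DKO TAM and 829 to 1438 for DKO and DKO TAM, and the top decile from -0.151 to -0.0639, -0.670 to -0.633 and -0.219 to -0.138. The descriptions number the libraries of each group 1 and 2, but deviations of libraries with the same number in their descriptions correlated at -0.07, 0.11 and -0.01 across genes; as a block the number gave 1924, 6860, 2411, 2924, 3575 and 145 genes.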

Other observations

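Of the tests below, that of gene length was fixed before its result was seen, and the values were chosen afterwards. Stress and inflammation genes moved unevenly in Gdown1-deleted livers. The acute phase gene Crp fell 4.75-fold in KO, 8.36-fold in DKO and 4.20-fold in DKO TAM livers, while the adhesion gene Icam1 rose 2.49-fold, 4.30-fold and 1.90-fold. Vcam1, another adhesion gene, rose 2.03-fold in KO and 6.99-fold in DKO livers. The inflammation and acute phase list as a whole was not called (adjusted p = 0.21, 0.24 and 0.18), with 2 higher and 2 lower, 10 and 5, and 2 and 4 of 29 genes, the same adjusted over the list alone. It passed for KO without FF replicate 1 (0.047) and for DKO TAM without DKO TAM replicate 2 (0.0049). G6pdx, of the pentose phosphate pathway, rose 5.20-fold in KO and 5.63-fold in DKO livers. In KO livers the antioxidant regulator Nfe2l2 rose 2.20-fold, in DKO livers Hmox1, a heme oxygenase, 4.27-fold, and in DKO TAM livers the transporter Abcc3 fell 3.06-fold. Of 28 NRF2 genes, 6 rose and 5 fell in KO (7 and 5 adjusted over the list alone), 14 and 8 in DKO (14 and 8) and 1 and 5 in DKO TAM (2 and 5), with adjusted p = 0.097, 0.082 and 0.074. The list passed for KO without KO replicate 1 (0.0020) and for DKO TAM without p53KO TAM replicate 2 (0.018) or DKO TAM replicate 1 (0.0069).

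Of 20 clock genes, 2 rose and 4 fell in KO (3 and 8 adjusted over the list alone; list adjusted p = 0.12), 2 rose and 11 fell in DKO (3 and 12; adjusted p = 0.22 with an estimated correlation, and 0.086 without p53KO replicate 2; 5 and 5 with library totals alone, with the median moving from -0.90 to -0.13), and 1 rose and 4 fell in DKO TAM (1 and 4; list adjusted p = 0.80; 8 and 0 with library totals alone, with a median of 0.50). Arntl and Npas2, which drive the clock, rose 4.04-fold and 5.35-fold in KO livers. Npas2 fell 1.97-fold in DKO TAM livers, a call lost without p53KO TAM replicate 2 or DKO TAM replicate 1 (adjusted p = 0.22 for both) and with DESeq2 or library totals alone (0.11 for both). Of 23 immediate early genes, 3 rose and 1 fell in KO (4 and 2 adjusted over the list alone; adjusted p = 0.44 with an estimated correlation, and 0.13 with library totals alone), 7 and 6 in DKO (7 and 7; list adjusted p = 0.88) and 1 and 1 in DKO TAM (1 and 1; 0.80). Unfolded protein response genes were not called in KO (1 higher and 6 lower of 26, 2 and 7 adjusted over the list alone; adjusted p = 0.077, and 0.041 without KO replicate 2) or DKO (7 and 15, the same adjusted over the list alone; 0.22), where library totals alone gave 10 higher and 2 lower and turned the median from -0.61 to 0.15. In KO livers the lymphocyte, neutrophil, erythroid, and adipocyte and pancreas lists were not called (adjusted p = 0.82, 0.71, 0.56 and 0.83), nor in DKO TAM livers (0.31, 0.25, 0.71 and 0.32), where the neutrophil list passed without DKO TAM replicate 2 (0.038). The adipocyte and pancreas list, with 3 genes measured, was not called in DKO livers (0.72).

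Control livers differed between experiments. The acute phase genes Saa1 and Lcn2 stood at 14.2 and 2.83 CPM in p53KO, 159 and 8.64 in FF and 845 and 608 in p53KO TAM livers. The male-biased genes Hsd3b5 and Elovl3 stood at 317 and 151, 347 and 99.3, and 25.6 and 1.47 CPM, and the female-biased genes Cyp2b9 and Cyp17a1 at 0.534 and 6.50, 1.08 and 5.92, and 147 and 131 CPM in the same order.

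A hypothesis was that transcripts of long genes fall more, because a protein bound to the elongating polymerase was lost. It was not borne out: Spearman's rho between log2 fold change and genomic length across genes was -0.0322 for KO, 0.00277 for DKO and -0.0176 for DKO TAM livers, where a value under -0.1 in each had been set as the sign of it.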
